A study of Caenorhabditis elegans with 22 samples.

How the data were processed

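RNA was sequenced from whole adult Caenorhabditis elegans in 22 libraries. Per the labels, animals lived on agar plates with 100 nM rotenone or with the solvent DMSO and were taken 1, 5, 10 or 20 days after L4, the last larval stage. Each treatment had 3 libraries at days 1, 5 and 10 and 2 at day 20. Per the labels' protocols, total RNA was extracted with QIAzol and 2 μg per sample entered the TruSeq RNA library kit. Libraries of this kit do not mark the strand, so overlapping genes on opposite strands were not separated. The labels do not state whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

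The authors deposited 1 table of read counts per gene and 1 table of RPKM. Per the labels, the counts are whole numbers of reads without normalization, and the submitters' processing notes name TopHat 1.4.1, HTSeq and genome build WBcel235 without giving their role or order. Neither the annotation version nor any filter on reads is stated. The deposited RPKM values equal the count divided by the library's total count and by 1 length per gene, with a largest relative deviation of that length of 6.9e-15. Those lengths did not match the exonic lengths of the annotation. Over 16555 genes the Spearman correlation was 0.137 across genes, and 56.5% of the genes differed by over 2-fold. For unc-54 the implied length was 191 bases and the exonic length 6204 bases. RPKM values were therefore used in no test, and every column of counts was used.

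The count table held 45461 genes, of which 28814 had at least 1 count. Identifiers of 44080 genes and of 16533 of the 16822 tested genes were matched to RefSeq genes of the same genome build, which gave coordinates and current names. Exonic lengths came from a separate Ensembl annotation of that build and were found for 16555 of the tested genes. Gene names are printed as in the table, with the current name where it differs. Gene lists were matched by current name first.

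Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 16822, and libraries were scaled by TMM. All 8 groups entered 1 fit, and rotenone was compared with DMSO at each age, DMSO at each later age with DMSO at day 1, and the rotenone effect at each later age with that at day 1 as an interaction. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene passed at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. CPM are counts scaled to the library's total count over tested genes times its TMM factor, given as mean ± SD over libraries. Total counts ran from 25769159 to 69961601 per library. The common biological coefficient of variation was 0.135.

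The comparisons, 32 gene lists, 6 single genes, the rule for named genes and most alternatives were chosen before the data were examined. The rule named up to 8 genes per direction in each rotenone comparison, with the largest fold changes among those with adjusted p under 0.05, a mean of at least 20 counts and no overlap of CPM between the groups. By chance 10% of genes do not overlap for 3 libraries against 3, and 1 in 3 for 2 against 2. It named up to 6 per direction for age and up to 4 per direction for the interaction. It also named the 2 members with the smallest p in the list's direction for up to 8 passing lists per comparison, and the 6 single genes. Genes named outside this rule were chosen after their values were seen.

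Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, which compares the members with all other genes. P-values were adjusted within 3 families: 32 lists at 4 ages of rotenone, at 3 ages of DMSO and for 3 interactions. The test was repeated with the correlation estimated from the data, and with fry, which asks whether the members move 1 way on balance without reference to other genes. Counts of list members that passed are given over all 16822 genes and adjusted over the list alone.

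Alternatives were RLE size factors, no filter, a mean of at least 50 counts, the replicate number as a term in the model, DESeq2 1.42.0, a fit of only the groups compared, and each library left out in turn. After the data were seen, these were added: the replicate number as a separate term at each day, a smooth trend on exonic length removed from each library (lowess span 0.3), both together, and DMSO day 10 replicate 1 left out of comparisons it is not part of. Deviations from the group mean across genes had a correlation of 0.43, 0.22 and 0.16 between DMSO and rotenone libraries with the same replicate number at day 10. Unequal numbers gave -0.39 to 0.24, with 0.24 for DMSO 2 and rotenone 3 and 0.17 for DMSO 3 and rotenone 2, so only the pair of replicate 1 stood out. Since each of the 3 equal pairs was over 0.1, a fit with a replicate term was given. Whether the numbers pair these libraries stays open, since the labels do not state it. Values with the replicate term are given beside the day 10 results they change. Fits were tested on data simulated from the same counts without a length trend. At day 1, 83.6% of 67 genes given a 2-fold and 32.8% of 67 given a 1.5-fold change were recovered. At day 20 the shares were 74.6% and 26.9%, for simulated genes only.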

Results

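The libraries measured messenger RNA of whole adult worms in 8 groups, DMSO and rotenone at 1, 5, 10 and 20 days after L4. Groups held 3 libraries (n = 3) at days 1, 5 and 10 and 2 libraries (n = 2) at day 20. Rotenone is an inhibitor of respiratory complex I, which passes electrons from NADH to ubiquinone. Total counts at day 1, in units of 1e+06 reads, were 48.8, 57.8 and 38.7 for DMSO and 27.2, 57.7 and 31.3 for rotenone. They were 37.6, 49.6 and 33.8 for DMSO and 64.6, 31.3 and 28 for rotenone at day 5, and 27.1, 60, 50.1 and 51.7, 56.9, 70 at day 10. At day 20 they were 51 and 25.8 for DMSO and 65.8 and 33.1 for rotenone. The first principal component held 50.2% of the variance and the second 27.8%, and both separated the ages. The third held 7.17%, and DMSO day 10 replicate 1 lay at -77.3 on it, against -10.8 for replicate 2 of its group. The ribosomal RNA gene rrn-3.1 took 17.56% of the counts of rotenone day 5 replicate 2.

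**Figure D1:**
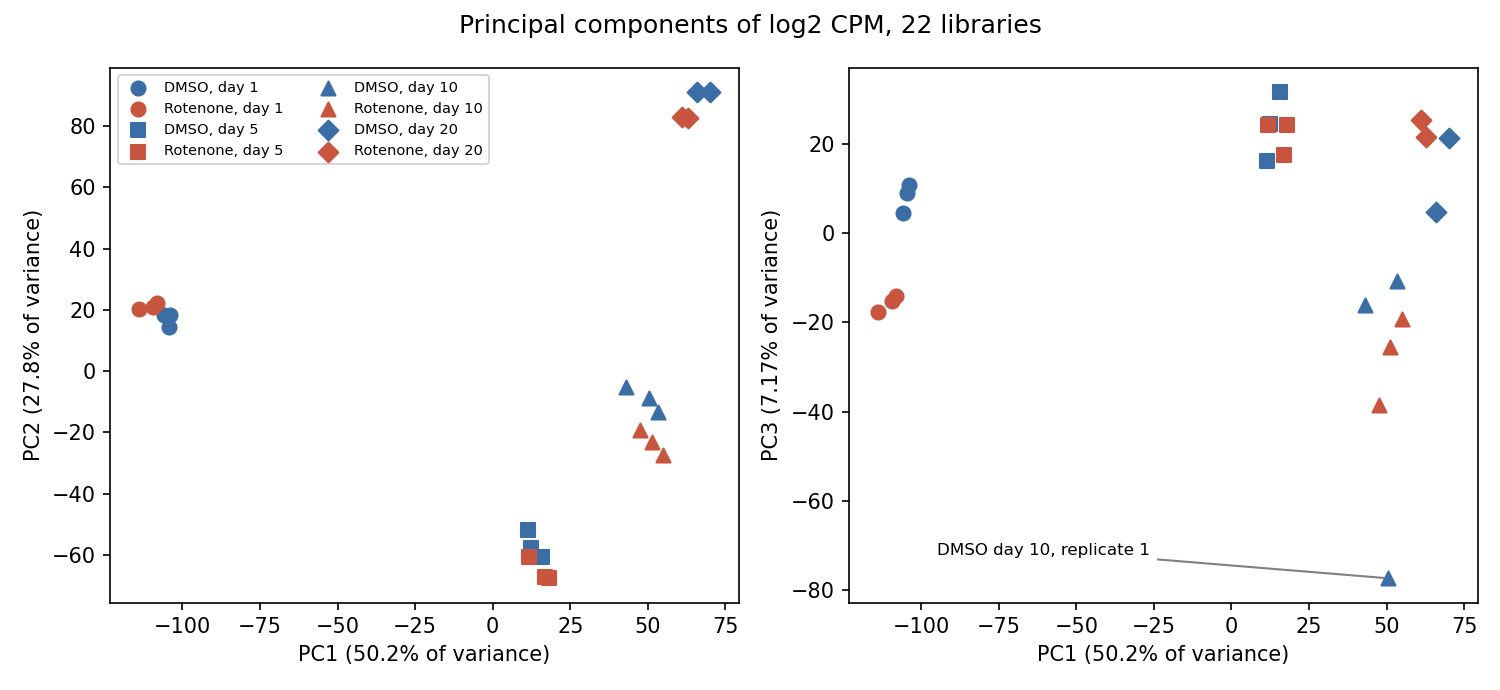
Principal components of log2 CPM for 22 libraries, with the first component against the second and the first against the third. Each point is a library, libraries lie together by age, and DMSO day 10 replicate 1 lies apart at -77.3 on the third component.

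How the transcriptome of animals on the solvent DMSO changed with age was asked by comparing DMSO libraries at each later age with those at day 1. Most genes of the cuticle and of muscle fell with age, and each of the 6 yolk protein genes had fallen by day 20. The adult cuticle collagen col-19 (X, 421707 to 422691) fell from 1640 ± 33 CPM (SD, n = 3) at day 1 to 75.4 ± 2.1 CPM (SD, n = 3) at day 5, a log2 fold change of -4.44 ± 0.14 (SE, n = 3 per group). The collagen col-119 (IV, 8978926 to 8979795) fell from 3140 ± 190 CPM (SD, n = 3) to 100 ± 6 CPM (SD, n = 3) at day 10 and 54.8 ± 4.7 CPM (SD, n = 2) at day 20. The muscle myosin light chain mlc-3 (III, 5565025 to 5567007) was at 494 ± 27 CPM (SD, n = 3) at day 1 and at 84.4 ± 3 and 56.7 ± 2.5 CPM (SD, n = 3 and 2) at days 10 and 20, and passed the test at each later age. The yolk protein gene vit-2 (X, 5101032 to 5106169) fell from 11600 ± 1100 CPM (SD, n = 3) to 1780 ± 630 CPM (SD, n = 2) at day 20, a log2 fold change of -2.7 ± 0.29 (SE).

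Of 155 tested collagens, 106 fell and 16 rose at day 5, 126 fell and 13 rose at day 10, and 125 fell and 13 rose at day 20. The list's adjusted p was 1.2e-10, 1.4e-24 and 1.5e-21 with the preset correlation, and its adjusted p with an estimated correlation was 0.26, 0.16 and 0.16. Every tested muscle gene of the list, 20 of 20, fell at day 5, with a median log2 change of -1.98 (adjusted p = 8.7e-12, and 0.19 with an estimated correlation), and 19 of 20 fell at day 20, with a median of -2.96 (adjusted p = 6.5e-11, and 0.19 with an estimated correlation). At day 20 the muscle troponin I gene unc-27 (X, 8789456 to 8790621) stood at 32.7 ± 4 CPM (SD, n = 2) against 566 ± 20 CPM (SD, n = 3) at day 1. Of 34 sperm genes 30 fell at day 5, with a median log2 change of -4.52 (adjusted p = 6.5e-11, and 0.16 with an estimated correlation). Of 82 cytosolic ribosomal protein genes 78 fell at day 5 and 76 at day 20 (adjusted p = 1e-10 and 1.2e-10, and 0.47 and 0.47 with an estimated correlation).

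Genes of the respiratory chain fell with age as well. Of 21 nuclear complex I genes 16, 15 and 19 fell at days 5, 10 and 20 in edgeR and none rose. The list's adjusted p by camera was 0.0011, 0.0012 and 4.5e-06, and 0.32, 0.32 and 0.19 with an estimated correlation. The complex I genes D2030.4, now ndub-7 (I, 7580944 to 7581628), and T20H4.5, now ndus-8 (III, 7232926 to 7234202), fell at day 20 with log2 fold changes of -1.31 ± 0.11 and -1.05 ± 0.09 (SE). The complex I gene gas-1 fell at each age, by 0.77, 1.12 and 1.32 on the log2 scale. At day 20, 31 of 33 genes of complexes II to V fell (adjusted p = 9e-07, and 0.22 with an estimated correlation), among them the complex III gene ucr-2.2 and the ATP synthase gene asb-2 with log2 fold changes of -1.35 ± 0.08 and -1.39 ± 0.11 (SE). The mitochondrial chaperone hsp-6 did not pass at any age, with adjusted p of 0.45, 0.95 and 0.74.

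Other groups rose or fell with age. Of 90 immune effector genes 50 rose and 24 fell at day 5, with a median log2 change of 0.97 (adjusted p = 4e-05, and 0.47 with an estimated correlation). The lysozyme gene lys-7 (V, 3481432 to 3482600) rose from 92.5 ± 4.2 CPM to 1660 ± 61 CPM (SD, n = 3), a log2 fold change of 4.17 ± 0.12 (SE). Of 75 cytochrome P450 genes 37 rose and 14 fell at day 5 (adjusted p = 0.00018, and 0.26 with an estimated correlation), and cyp-34A2 (V, 15288777 to 15291095) rose from 0.944 ± 0.23 CPM to 17.7 ± 1.9 CPM (SD, n = 3). Of 24 oocyte and eggshell genes 18 rose and 1 fell at day 5 (adjusted p = 3.1e-05, and 0.26 with an estimated correlation). The intestinal actin act-5 (III, 13604412 to 13606066) fell from 504 ± 14 CPM to 43.5 ± 11 CPM (SD, n = 3) at day 10, and 9 of 11 intestinal genes fell there and 1 rose (adjusted p = 0.0012, and 0.39 with an estimated correlation). Of 6 vitellogenins 4 fell at day 5 and 1, vit-5, rose, from 2780 ± 460 to 5090 ± 1900 CPM (SD, n = 3, adjusted p = 0.037, list adjusted p = 0.18). The call of vit-5 was lost without DMSO day 1 replicates 1 and 2 and DMSO day 5 replicate 3 (adjusted p = 0.074, 0.13 and 0.23). Among the 4 that fell, vit-2 had adjusted p = 0.037 and lost its call without DMSO day 1 replicates 1 and 3 and DMSO day 5 replicates 1 and 2 (adjusted p = 0.067, 0.11, 0.091 and 0.17). At day 20, 6 of 6 vitellogenins fell (adjusted p = 9.3e-05, and 0.26 with an estimated correlation), and 13 of 19 neuronal genes rose and 1 fell (adjusted p = 0.016, and 0.45 with an estimated correlation).

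In edgeR 9413 of 16822 genes passed at day 5 (4145 higher, 5268 lower), 9464 at day 10 (4493 higher, 4971 lower) and 9871 at day 20 (4681 higher, 5190 lower). The gene lists gave 52 calls in 3 ages, 14 higher and 38 lower, of which 0 held with an estimated correlation. Counted separately, fry gave 79 calls. The 3 ages share the day 1 libraries, so their results are not independent.

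The effect of rotenone at day 1 was asked by comparing rotenone with DMSO 1 day after L4. The largest rise was in the glutathione S-transferase gst-14 (II, 13614781 to 13616100), which rose from 0.074 ± 0.041 to 1.46 ± 0.51 CPM (SD, n = 3), a log2 fold change of 4.11 ± 0.46 (SE, adjusted p = 9.6e-05). The cytochrome P450 gene cyp-14A4 (X, 13282043 to 13284197) rose from 0.292 ± 0.17 to 1.27 ± 0.19 CPM (SD, n = 3), a log2 fold change of 2.11 ± 0.33 (SE, adjusted p = 0.0043). F22B5.4 (II, 8449710 to 8452742), a gene induced by the hypoxia factor HIF-1, rose by 2 ± 0.22 (SE) on the log2 scale, from 0.709 ± 0.13 to 2.91 ± 0.7 CPM (SD, n = 3). F09G2.3, now pitr-5 (V, 7184850 to 7188483), a phosphate transporter gene, rose from 3.57 ± 0.18 to 12.9 ± 3.8 CPM (SD, n = 3), and B0205.13 (I, 10727755 to 10728759) from 1.19 ± 0.26 to 5.05 ± 0.56 CPM (SD, n = 3). The short-chain dehydrogenase dhs-26 (X, 3360722 to 3362493) fell from 1.98 ± 0.22 to 0.873 ± 0.12 CPM (SD, n = 3), a log2 fold change of -1.21 ± 0.14 (SE, adjusted p = 0.00016).

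Fold changes at day 1 followed gene length, with a Spearman correlation of -0.536 across 16555 genes, which are not independent replicates. The median log2 change was 0.26 in the fifth of genes with the shortest exons (median 549 bases) and -0.26 in the fifth with the longest (median 3013 bases). The groups below are therefore given with and without this trend, a setting chosen after the data were seen.

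**Figure D2:**
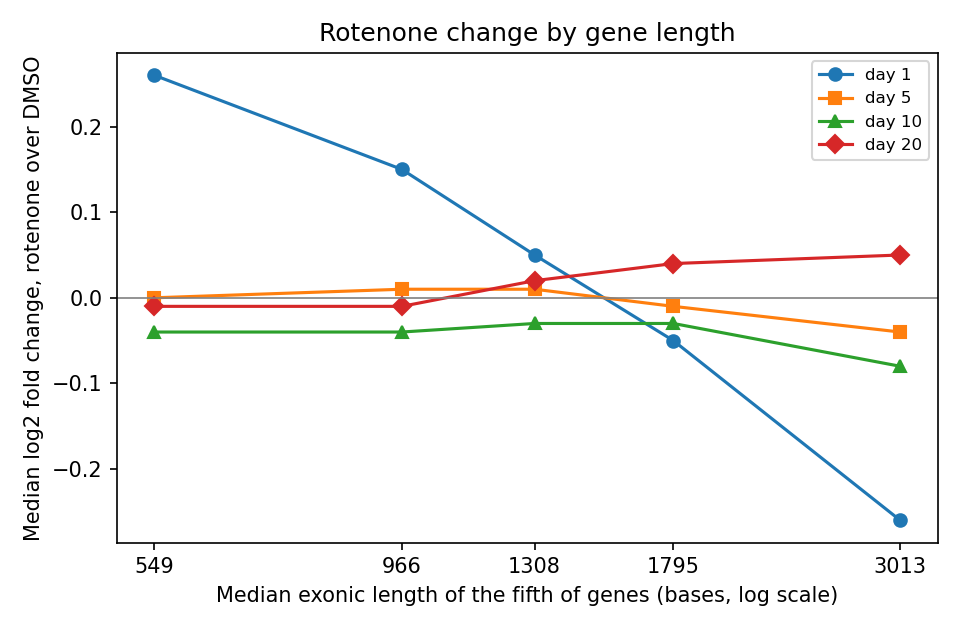
Median log2 fold change of rotenone over DMSO at 4 ages against the median exonic length (bases, log scale) of 5 equal sets of genes. The day 1 line falls from 0.26 at 549 bases to -0.26 at 3013 bases, and the lines of days 5, 10 and 20 stay between -0.08 and 0.05.

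Among 46 glutathione S-transferase and glutathione synthesis genes 2 rose and none fell, and 5 rose when adjusted over the list alone. The median log2 change was 0.21 (adjusted p = 0.00012), the adjusted p with an estimated correlation was 0.64, and with the length trend removed the median was 0.02 (adjusted p = 0.21). Of the 46, 9 rose and 1 fell without DMSO day 10 replicate 1. The members that rose with all libraries were gst-14 and gst-19 (II, 13625545 to 13627145), the latter by 1.56 ± 0.33 (SE) on the log2 scale with adjusted p = 0.032. Among 23 P-glycoprotein and other ABC exporters, which pump compounds out of cells, 2 fell, 3 fell when adjusted over the list alone, and 9 fell without DMSO day 10 replicate 1. Their median log2 change was -0.29 (adjusted p = 1.8e-05, and 0.78 with an estimated correlation), and with the length trend removed it was 0.08 (adjusted p = 0.54). The exporter pgp-5 (X, 10854216 to 10859297) fell from 7.51 ± 0.63 to 4.58 ± 0.4 CPM (SD, n = 3) and its neighbour pgp-6 (X, 10871201 to 10877425) from 4.27 ± 0.086 to 2.02 ± 0.32 CPM (SD, n = 3). With the length trend removed the log2 fold change of pgp-5 went from -0.72 to -0.38 (adjusted p = 0.15).

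Of the other lists called at day 1, vitellogenins (median log2 change -0.47, 0 of 6 passed, 1 lower when adjusted over the list alone), germline genes (-0.22, 0 of 25 passed), endoplasmic reticulum unfolded protein response genes (-0.15, 0 of 20 passed), autophagy genes (-0.09, 0 of 26 passed, 3 lower over the list alone) and intestinal genes (-0.2, 0 of 11 passed, 1 higher and 1 lower over the list alone) were lower. Sperm genes (0.35, 0 of 34 passed), histones (0.21, 0 of 26 passed), collagens (0.25, 1 of 155 rose, 10 higher and 5 lower over the list alone) and immune effectors (0.17, 4 of 90 rose, 9 higher and 1 lower over the list alone) were higher. Their adjusted p ran from 0.0015 to 0.033, the adjusted p with an estimated correlation was 0.78 for each, and with the length trend removed the adjusted p was between 0.067 and 0.64. The medians of immune effectors and histones were then -0.07 and -0.04, so their direction turned. Autophagy genes (-0.08), intestinal genes (-0.16) and collagens (0.15) stayed nearest to their medians, while those of vitellogenins (-0.07), germline genes (-0.06), unfolded protein response genes (-0.04) and sperm genes (0.08) moved close to 0. In the fit without DMSO day 10 replicate 1, 11 germline, 7 unfolded protein response, 9 autophagy, 4 intestinal and 2 vitellogenin genes were lower, and 1 intestinal gene was higher. Of collagens 19 were then higher and 6 lower, of immune effectors 12 higher and 3 lower, and of sperm genes and histones 2 and 1 higher. Ribosomal protein genes had a median log2 change of 0.15 (0 of 82 passed, adjusted p = 0.0065, and 0.81 with an estimated correlation), and of -0.1 with the length trend removed (adjusted p = 3.2e-05), so their direction turned with that setting. Genes of branched-chain amino acid catabolism (-0.1, 0 of 13 passed, adjusted p = 0.042) and proteasome genes (-0.03, 0 of 33 passed, adjusted p = 0.046) kept their direction with the trend removed (adjusted p = 0.048 and 1.9e-06), and their adjusted p with an estimated correlation was 0.78 and 0.79. Of the 13 and the 33 genes, 3 and 5 were lower without DMSO day 10 replicate 1. The vitellogenin vit-1 was at 1940 ± 130 CPM with rotenone and 3150 ± 430 CPM with DMSO (SD, n = 3, adjusted p = 0.16), and shares sequence with other vitellogenins, as do members of the histone and sperm protein families.

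Nuclear complex I genes had a median log2 change of 0.06 (0 of 21 passed, adjusted p = 0.77), and of -0.13 with the length trend removed (adjusted p = 0.0071, and 0.76 with an estimated correlation). No call was made for the mitochondrial unfolded protein response (-0.12, 0 of 13 passed, adjusted p = 0.22), antioxidant enzymes (0.03, 1 of 24 rose, adjusted p = 0.65), mitochondrially encoded mRNAs (0.19, 0 of 8 passed, adjusted p = 0.25) or complexes II to V (0.16, 0 of 33 passed, adjusted p = 0.15). Without DMSO day 10 replicate 1 none of these lists was called either, while 5 of 13 mitochondrial unfolded protein response genes were lower and none higher (median -0.14, adjusted p = 0.12). Of antioxidant enzymes 2 were then higher and 3 lower, of complexes II to V 2 and 2, of complex I 1 and 1, and of mitochondrially encoded mRNAs 1 was higher. The mitochondrial chaperones hsp-6 and hsp-60, the detoxification gene gst-4, the superoxide dismutase sod-3 and gas-1 had log2 fold changes of -0.34, -0.11, 0.07, 0.03 and -0.11 (adjusted p = 0.36, 0.74, 0.78, 1 and 0.51).

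In edgeR 109 genes passed at day 1, 63 higher and 46 lower, and 97 passed with the length trend removed, of which 66 were shared. With no filter 1822 passed (542 higher), with the replicate term at each day 2075 (643 higher, 1432 lower), in DESeq2 314 (137 higher, 177 lower) and in a fit of only these groups 5010 (2156 higher, 2854 lower), so the balance turned to more lower genes. In data simulated with a length trend (correlation -0.628) the fit called 339 unchanged genes, 4 with it removed, against 2 without a trend. The count was 39, 44 and 26 without DMSO day 1 replicates 1, 2 and 3, 46 and 22 without rotenone day 1 replicates 1 and 3, and 3082 (806 higher, 2276 lower) without DMSO day 10 replicate 1, which enters through the shared spread. Of 18 named genes that passed, 8 also passed in every alternative: gst-14, cyp-14A4, B0205.13, F22B5.4, F09G2.3, pqn-74, R09E10.5 and dhs-26. The calls of F45E4.7, ZC317.7 and gst-19 were lost without any 1 of the 6 libraries (adjusted p from 0.08 to 0.23, 0.074 to 0.24 and 0.069 to 0.21). Those of ZC84.6 and pgp-6 were lost without any but rotenone replicate 2 (0.098 to 0.24 and 0.054 to 0.11), and that of F47C12.1 without any but DMSO replicate 2 (0.053 to 0.11). Y9C9A.16 lost its call without DMSO replicates 1 and 3 and rotenone replicates 2 and 3 (0.055 to 0.11), and C01G10.4 without DMSO replicates 1 and 3 and rotenone replicate 3 (0.065 to 0.073). The call of lys-10 was lost without DMSO replicate 3 (0.052) and that of pgp-5 without rotenone replicate 3 (0.058). The lists of glutathione S-transferases, ABC exporters, unfolded protein response, vitellogenins, germline genes and histones kept their call with each library of the comparison left out. The other 8 did not. Without DMSO replicate 1 the adjusted p was 0.059 for branched-chain amino acid catabolism, 0.068 for ribosomal proteins and 0.096 for the proteasome, which had 0.051 without DMSO replicate 2. Without DMSO replicate 3 it was 0.054 for immune effectors, 0.072 for branched-chain amino acid catabolism and 0.05 for autophagy genes. Without rotenone replicate 1 it was 0.085 for intestinal genes, 0.058 for branched-chain amino acid catabolism and 0.2 for the proteasome. Without rotenone replicate 2 immune effectors, collagens, intestinal genes, branched-chain amino acid catabolism and ribosomal proteins had 0.051, 0.11, 0.063, 0.059 and 0.15. Without rotenone replicate 3 sperm genes, ribosomal proteins and autophagy genes had 0.081, 0.14 and 0.062.

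The effect of rotenone at day 5 was asked in the same way. The gene dod-23 (II, 8398161 to 8399164), which lies downstream of the insulin pathway factor DAF-16, rose from 184 ± 7.4 to 517 ± 24 CPM (SD, n = 3), a log2 fold change of 1.49 ± 0.11 (SE, adjusted p = 3.7e-07). The cathepsin B-like protease cpr-5 (V, 1132598 to 1134036) rose from 46.4 ± 1.1 to 84.4 ± 5.5 CPM (SD, n = 3), and oac-54 (II, 9158111 to 9159984), an acyltransferase gene of the HIF-1 list, from 2.46 ± 0.14 to 5.05 ± 0.32 CPM (SD, n = 3). The cuticle collagen gene rol-1 (II, 12172573 to 12176069) fell from 3.17 ± 0.35 to 0.177 ± 0.13 CPM (SD, n = 3), a log2 fold change of -4.53 ± 0.36 (SE, adjusted p = 1.1e-06). The collagen col-49 (I, 3137185 to 3138447) fell from 2.13 ± 0.094 to 0.15 ± 0.17 CPM (SD, n = 3), and col-138 (IV, 17182884 to 17183729) from 4.08 ± 0.38 to 0.437 ± 0.33 CPM (SD, n = 3).

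**Figure D3:**
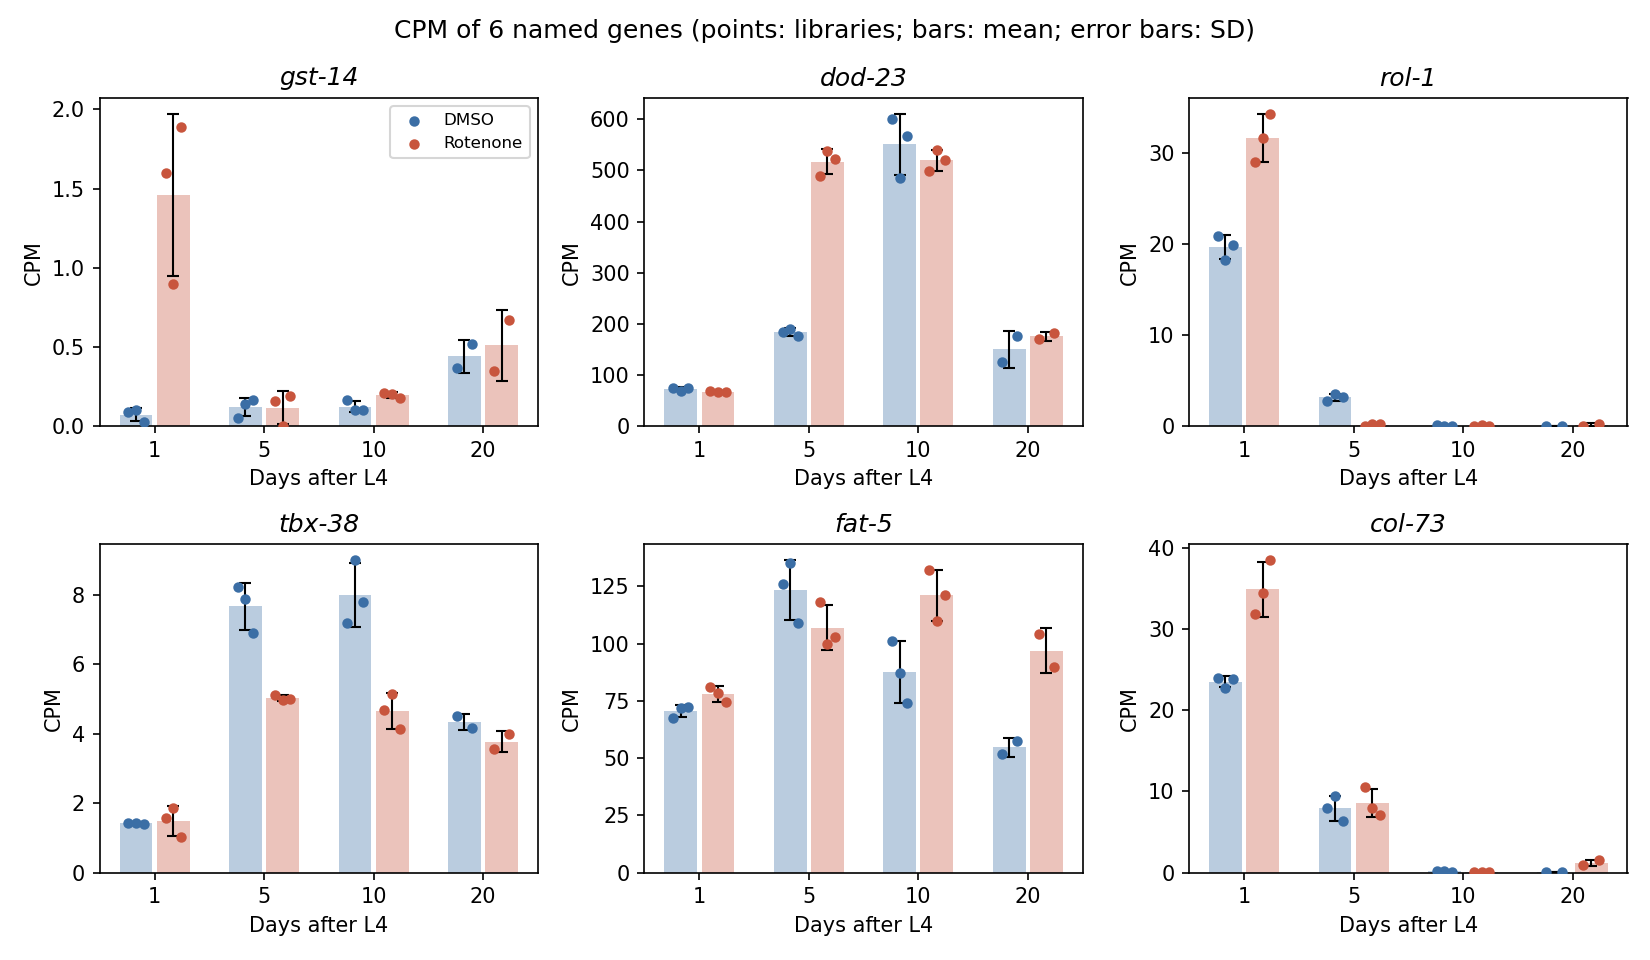
CPM of gst-14, dod-23, rol-1, tbx-38, fat-5 and col-73 at 1, 5, 10 and 20 days after L4 in DMSO and rotenone libraries. Points are libraries, bars are means and error bars are SD; dod-23 at day 5 stands at 517 CPM with rotenone and 184 CPM with DMSO.

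Of 155 tested collagens 13 fell and none rose, and 15 fell when adjusted over the list alone. Their median log2 change was -0.07 and their mean -0.29 (adjusted p = 0.028, and 0.79 with an estimated correlation). The fallen collagens included col-175, col-63, col-112 (now bli-6) and col-88, with log2 fold changes between -3.36 and -4.03. Without DMSO day 5 replicates 1 and 2 the adjusted p of the list was 0.097 and 0.25, and without rotenone day 5 replicates 2 and 3 it was 0.13 and 0.38.

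Of 37 early embryo genes, which are transcribed from the embryo's own genome, 4 fell and none rose, and 11 fell when adjusted over the list alone. The median log2 change was -0.34 and 29 of 37 members were lower (adjusted p = 5.4e-07, and 0.023 with an estimated correlation). Without DMSO day 10 replicate 1, 6 fell, the median was -0.33 and the adjusted p with an estimated correlation 0.13. The zygotic transcript gene sdz-28 (II, 2131070 to 2132475) fell from 13.9 ± 0.6 to 9.12 ± 0.44 CPM (SD, n = 3), a log2 fold change of -0.61 ± 0.1 (SE, adjusted p = 0.0026), and sdz-14 (I, 12216252 to 12217772) from 7.98 ± 0.68 to 5.3 ± 0.35 CPM (SD, n = 3). The oocyte and eggshell list had a median log2 change of 0.02 (1 of 24 fell, adjusted p = 0.95).

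Of 10 genes induced by DAF-16, 1 fell, dod-3, and 4 fell when adjusted over the list alone, with a median log2 change of -0.53 (adjusted p = 0.0019, and 0.2 with an estimated correlation). Of 90 immune effectors 4 fell, and 12 fell when adjusted over the list alone (median log2 change -0.14, adjusted p = 0.0019, and 0.78 with an estimated correlation). Without DMSO day 5 replicate 2 the adjusted p of that list was 0.098. When DMSO day 10 replicate 1 was left out, 12 immune effectors and 3 genes induced by DAF-16 fell, and 1 of 20 muscle genes rose. The thaumatin family gene thn-2 (IV, 12383170 to 12383974) fell from 169 ± 23 to 110 ± 3.3 CPM (SD, n = 3), a log2 fold change of -0.62 ± 0.11 (SE, adjusted p = 0.0079), and its neighbour thn-1 (IV, 12380084 to 12380900) from 6.44 ± 1.3 to 3.63 ± 0.24 CPM (SD, n = 3). With all libraries no gene of the sperm, muscle, proteasome, unfolded protein response or glycolysis lists passed. Their median log2 changes were -0.87, 0.06, -0.08, -0.15 and -0.14 (adjusted p = 0.036, 0.028, 0.036, 0.037 and 0.046, each with adjusted p = 0.78 with an estimated correlation). Without DMSO replicate 1 muscle, proteasome, unfolded protein response and glycolysis genes had adjusted p of 0.1, 0.055, 0.061 and 0.12. Without DMSO replicate 2 sperm and muscle genes had 0.29 and 0.23, and without DMSO replicate 3 proteasome, unfolded protein response and glycolysis genes had 0.1, 0.38 and 0.14. Without rotenone replicate 1 sperm, muscle and unfolded protein response genes had 0.11, 0.1 and 0.12. Without rotenone replicate 2 sperm, proteasome, unfolded protein response and glycolysis genes had 0.063, 0.27, 0.089 and 0.18, and without rotenone replicate 3 muscle, proteasome and glycolysis genes had 0.067, 0.059 and 0.067. Complex I genes had a median log2 change of -0.02 (0 of 21 passed, adjusted p = 0.9), and hsp-6, hsp-60, gst-4, sod-3, gas-1 and vit-2 had adjusted p of at least 0.91.

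In edgeR 148 genes passed at day 5, 18 higher and 130 lower. The count was 83, 50 and 97 without DMSO day 5 replicates 1, 2 and 3, 66, 46 and 80 without rotenone day 5 replicates 1, 2 and 3, 308 without DMSO day 10 replicate 1 and 339 with no filter. Of 21 named genes that passed, 14 passed in every alternative: dod-23, clec-82, oac-54, the acid phosphatase pho-13, cpr-5, F09C8.1, rol-1, col-49, col-175, col-63, col-112, col-138, T19D12.5 and sdz-28. The calls of col-88 and T05E12.7 (now srh-237) were lost without any 1 of the 6 libraries (adjusted p from 0.052 to 0.2 and 0.083 to 0.21), and that of dod-3 without any but DMSO replicate 3 (0.092 to 0.32). The gene thn-1 lost its call without DMSO replicate 2 and each rotenone library (0.066 to 0.2), and R09A1.5 (now flp-34) without DMSO replicates 2 and 3 and rotenone replicates 1 and 2 (0.13 to 0.21). The call of sdz-14 was lost without DMSO replicate 2 and rotenone replicates 1 and 2 (0.079 to 0.12), and that of thn-2 without DMSO replicate 2 and rotenone replicate 2 (0.087 and 0.064).

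The effect of rotenone at day 10 was asked in the same way, and DMSO day 10 replicate 1, which lay apart on the third component, belongs to this comparison. Of the P450 genes cyp-33C1 (V, 2179514 to 2181938) was at 2.93 ± 0.45 CPM with rotenone and 1.13 ± 0.33 CPM with DMSO, a log2 fold change of 1.39 ± 0.19 (SE, n = 3, adjusted p = 0.0017), and cyp-33B1 (V, 9041330 to 9043677) at 5.57 ± 1.4 and 2.56 ± 0.62 CPM (SD, n = 3). The collagen col-183 (X, 13466643 to 13467764) rose from 4.85 ± 0.69 to 11.1 ± 1.8 CPM (SD, n = 3). The infection response genes F35E12.5, now irg-5 (V, 13737010 to 13738474), and ZK6.11, now irg-8 (V, 415870 to 417706), rose from 34.1 ± 3.2 to 59.7 ± 9.7 and from 19.8 ± 1.2 to 29.8 ± 3.7 CPM (SD, n = 3). The T-box transcription factor tbx-38 (III, 11784082 to 11786061), active in early embryos, fell from 8 ± 0.92 to 4.65 ± 0.51 CPM (SD, n = 3), a log2 fold change of -0.79 ± 0.13 (SE, adjusted p = 0.0049), and sdz-28 fell from 12.4 ± 0.24 to 7.91 ± 0.96 CPM (SD, n = 3). Further falls were in tbx-40, the F-box genes fbxb-63 and fbxb-75, and btb-8, and further rises in C42D4.3 (now dbd-13), ZK355.3, grd-4, clx-1 and pqn-74.

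Of 37 early embryo genes 8 fell and none rose, and 16 fell when adjusted over the list alone. The median log2 change was -0.44 and 32 of 37 members were lower (adjusted p = 1.1e-09, and 0.0082 with an estimated correlation). Without DMSO day 10 replicate 1 the median was -0.28 (adjusted p = 0.00034, and 0.3 with an estimated correlation), and with the replicate number as a term at each day it was -0.44 (adjusted p = 9.5e-08, and 0.18 with an estimated correlation). Of 75 P450 genes 4 rose and none fell, and 9 rose when adjusted over the list alone (median 0.18, adjusted p = 3.4e-07, and 0.28 with an estimated correlation). Of the 75, 13 rose and none fell without DMSO day 10 replicate 1 (median 0.17, adjusted p = 0.0012, and 0.65 with an estimated correlation). Of 90 immune effectors 9 rose and none fell, 15 rose and 3 fell when adjusted over the list alone (median 0.11, adjusted p = 4.5e-05, and 0.78 with an estimated correlation), 29 rose and none fell without DMSO day 10 replicate 1 with a median of 0.37, and without DMSO day 10 replicate 3 the list's adjusted p was 0.072. Of 155 collagens 3 rose and 1 fell, and 6 rose and 1 fell when adjusted over the list alone (median 0.12, adjusted p = 0.00012, and 0.78 with an estimated correlation). Leaving out DMSO day 10 replicate 1, 19 collagens rose and 2 fell (median 0.29, adjusted p = 0.00027, and 0.65 with an estimated correlation). Without rotenone day 10 replicate 1 the collagen list had adjusted p = 0.13.

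**Figure D4:**
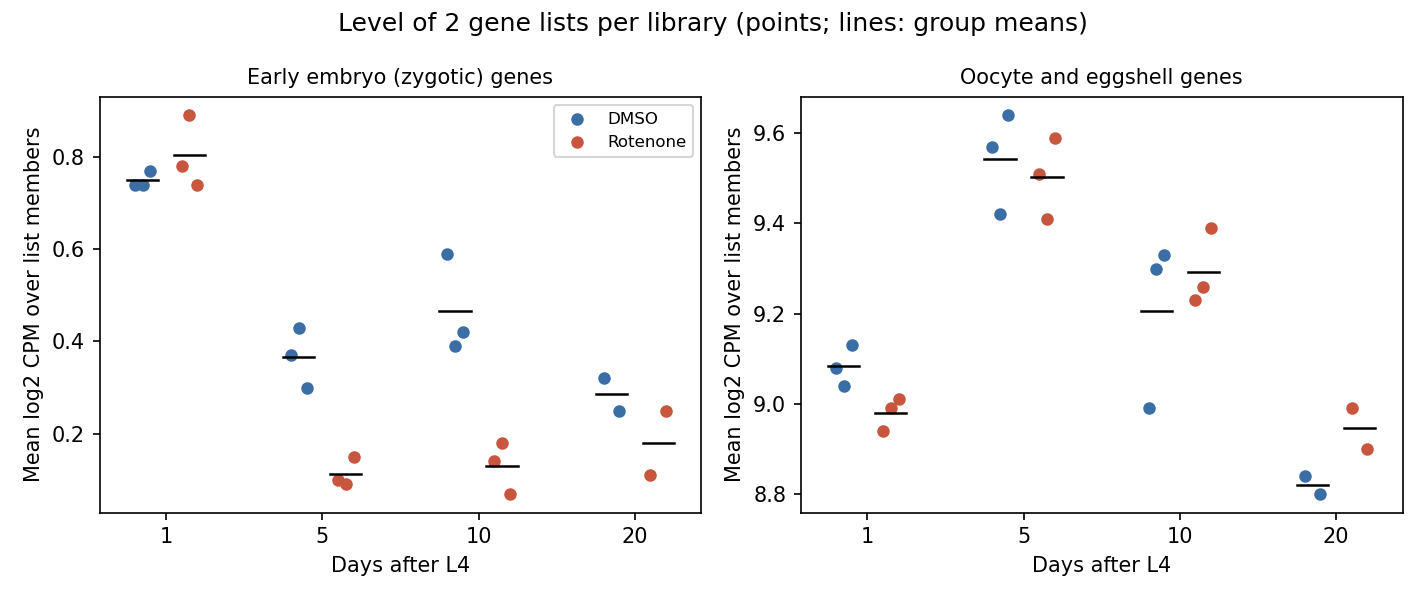
Mean log2 CPM over the 37 early embryo genes and over the 24 oocyte and eggshell genes per library at 4 ages. Points are libraries and lines are group means; the embryo list had a median log2 change with rotenone of -0.34 at day 5 and -0.44 at day 10, and the oocyte list of 0.02 and 0.07.

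Nuclear complex I genes had a median log2 change of -0.09 with 20 of 21 members lower, and 0 of 21 passed (adjusted p = 0.046, and 0.78 with an estimated correlation). The list was not called without DMSO day 10 replicates 1 and 3 (adjusted p = 0.29 and 0.12) or without rotenone day 10 replicate 1 (adjusted p = 0.48, where its direction turned). Proteasome genes (-0.09, 0 of 33 passed, adjusted p = 0.01), oocyte genes (0.07, 1 of 24 fell, adjusted p = 0.017), sperm genes (-0.44, 0 of 34 passed, adjusted p = 0.037), UDP-glucuronosyltransferases (0.06, 1 of 66 fell, adjusted p = 0.041) and DAF-16 induced genes (0.03, 0 of 10 passed, adjusted p = 0.046) each had adjusted p = 0.78 with an estimated correlation. Without DMSO replicate 1 the adjusted p was 0.44 for oocyte genes, 0.26 for UDP-glucuronosyltransferases and 0.095 for DAF-16 induced genes. In that setting 1 complex I, 2 proteasome and 4 sperm genes were lower, 3 DAF-16 induced genes higher, and of UDP-glucuronosyltransferases 4 higher and 1 lower. That fit, whose fold changes had a length correlation of -0.385, called further lists. Lower were the unfolded protein response (7 of 20, adjusted p = 6.3e-05), the citric acid cycle (3 of 15, 0.00027), ABC exporters (6 of 23, 0.00055), neuronal genes (4 of 19, 0.016) and autophagy genes (8 of 26 lower and 2 higher, 0.044). Higher were ribosomal proteins (0 of 82 passed, 0.00055), mitochondrially encoded mRNAs (3 of 8, 0.0028) and glutathione S-transferase genes (6 of 46 higher and 1 lower, 0.01). With an estimated correlation each had an adjusted p of at least 0.34. Without DMSO replicate 2 the adjusted p was 0.062 for the proteasome and 0.07 for DAF-16 induced genes. Without DMSO replicate 3 proteasome, sperm, UDP-glucuronosyltransferase and DAF-16 induced genes had 0.1, 0.93, 0.2 and 0.21. Without rotenone replicate 1 the proteasome had 0.48 and turned direction, and UDP-glucuronosyltransferases had 0.13. DAF-16 induced genes had 0.057 without rotenone replicate 2. Without rotenone replicate 3 oocyte, sperm, UDP-glucuronosyltransferase and DAF-16 induced genes had 0.16, 0.16, 0.064 and 0.15. With the replicate term sperm genes, UDP-glucuronosyltransferases and DAF-16 induced genes had adjusted p of 0.061, 0.053 and 0.064. Lists of complexes II to V, unfolded protein response, vitellogenins and histones then had 0.024, 0.026, 0.026 and 0.037, and at least 0.78 with an estimated correlation. None of hsp-6, hsp-60, gst-4, sod-3, gas-1 and vit-2 passed (adjusted p of at least 0.3).

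In edgeR 229 genes passed at day 10, 76 higher and 153 lower. A fit of only these 6 libraries called 0 genes, with 1855 at an unadjusted p under 0.05 in the fit of all groups and 371 genes passing in DESeq2, so no named gene passed in every alternative. The count was 2396 (1061 higher, 1335 lower), 135 and 102 without DMSO day 10 replicates 1, 2 and 3, 47 (30 higher, 17 lower) and 56 without rotenone day 10 replicates 1 and 3, and 349 (157 higher, 192 lower) with the length trend removed, of which 209 were shared. It was 648 (294 higher, 354 lower) with the replicate term as well, and 362 (169 higher, 193 lower) with no filter. Fold changes had a length correlation of -0.052, and -0.385 without DMSO day 10 replicate 1. In the alternatives that kept all 8 groups, the calls of C42D4.3, cyp-33C1, col-183, fbxb-63, btb-8, Y46G5A.28, sdz-28, F35E12.5 and ZK6.11 remained. Without any 1 library but DMSO replicate 1, dlc-3 and tab-1 lost their call (adjusted p from 0.069 to 0.16 and 0.082 to 0.19). Without each of DMSO replicates 2 and 3 and rotenone replicates 1 and 3, the calls of ZK355.3 (0.063 to 0.1), clx-1 (0.16 to 0.2), pqn-74 (0.071 to 0.17), tbx-40 (0.053 to 0.19), acs-3 (0.061 to 0.18) and col-101 (0.065 to 0.076) were lost. The call of grd-4 was lost without DMSO replicate 3 and rotenone replicates 1 and 3 (0.051 to 0.082), and that of tbx-38 without rotenone replicates 1 and 3 (0.066 and 0.05). The genes fbxb-75 and cyp-33B1 lost theirs without rotenone replicates 1 and 3 in turn (0.052 and 0.053). With the replicate term clx-1 and tab-1 had adjusted p of 0.085 and 0.062.

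The effect of rotenone at day 20 was asked with 2 libraries per group. The collagen col-73 (II, 4872098 to 4873129) was at 1.24 ± 0.38 CPM with rotenone and 0.0848 ± 0.022 CPM with DMSO (SD, n = 2), a log2 fold change of 3.69 ± 0.5 (SE, adjusted p = 0.0041). The cuticle collagens dpy-13 (IV, 4235617 to 4236710), dpy-5 (I, 5432197 to 5433051) and dpy-4 (IV, 14985543 to 14986784) rose with log2 fold changes of 2.84 ± 0.45, 2.83 ± 0.46 and 2.68 ± 0.43 (SE), from at most 0.533 ± 0.27 CPM to at least 3.32 ± 0.8 CPM (SD, n = 2). The fatty acid desaturases fat-6 (IV, 11913692 to 11915687) and fat-5 (V, 17725004 to 17726818) rose from 88.1 ± 4.8 to 146 ± 3.1 CPM and from 54.6 ± 4.2 to 97.1 ± 10 CPM (SD, n = 2). The gene col-81 fell, from 5.11 ± 3.8 to 1.22 ± 0.55 CPM (SD, n = 2).

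Of 155 collagens 6 rose and 1 fell, and 23 rose and 6 fell when adjusted over the list alone (median log2 change 0.17, adjusted p = 1.5e-06, and 0.78 with an estimated correlation). Of 28 larval cuticle and moulting genes 3 rose, the collagens dpy-4, dpy-5 and dpy-13, and 7 rose and 1 fell when adjusted over the list alone. Their median was -0.02, their mean 0.54 and the test's direction higher (adjusted p = 0.0025, and 0.78 with an estimated correlation), so median and test differed in sign. Without DMSO day 20 replicate 2 the adjusted p of these lists was 0.12 and 0.27. Of 41 fat metabolism genes 2 rose, and 8 rose when adjusted over the list alone (median 0.16, adjusted p = 1.8e-05, 0.2 with an estimated correlation and 0.53 without DMSO day 20 replicate 1). Of 17 heat shock response genes none passed in edgeR, and 1 rose when adjusted over the list alone. Their median was 0.24 with 16 of 17 higher (adjusted p = 0.0006, and 0.029 with an estimated correlation), and the adjusted p with an estimated correlation was 0.3 without DMSO day 10 replicate 1 and 0.24 with the length trend removed. The member hsp-70 stood at 18.8 ± 0.86 CPM with rotenone and 11 ± 1.5 CPM with DMSO (SD, n = 2, edgeR adjusted p = 0.5).

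Early embryo genes had a median log2 change of -0.21 (0 of 37 passed, adjusted p = 0.0019, and 0.2 with an estimated correlation). The remaining lists called at day 20 were higher with no member passing: ribosomal proteins (0.12), intestinal genes (0.23), proteasome (0.11), glycolysis (0.16), immune effectors (0.13), germline genes (0.16), the citric acid cycle (0.13), oocyte genes (0.14), vitellogenins (0.35), complex I (0.09) and muscle (0.17). Their adjusted p ran from 0.00012 to 0.044, and the adjusted p with an estimated correlation was at least 0.78. Of the 16 lists called, the heat shock list alone kept its call with each library of the comparison left out. Without DMSO replicate 1 the adjusted p was 0.086 for early embryo, 0.099 for glycolysis, 0.11 for germline, 0.27 for intestinal and 0.33 for citric acid cycle genes. Vitellogenins and muscle genes then turned direction, with adjusted p of 0.95 and 0.9. Without DMSO replicate 2 it was 0.066 for immune effectors, 0.15 for the proteasome, 0.47 for complex I and 0.6 for oocyte genes, and ribosomal proteins turned direction with adjusted p = 0.26. Without rotenone replicate 1 complex I, oocyte, germline and early embryo genes had 0.24, 0.45, 0.057 and 0.21, and glycolysis, citric acid cycle and ribosomal protein genes had 0.074, 0.19 and 0.2. Without rotenone replicate 2 vitellogenins and muscle genes had 0.4 and 0.27.

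In edgeR 11 genes passed at day 20, 10 higher and 1 lower. There were 37 in DESeq2, 64 with no filter, 20 with the replicate term at each day and 3 in a fit of only these groups. The count was 0 without DMSO day 20 replicate 1 and 0 without rotenone day 20 replicate 2, with 799 at an unadjusted p under 0.05 in the fit of all libraries, 63 without DMSO day 20 replicate 2 and 3 without rotenone day 20 replicate 1. Without those 2 libraries in turn the calls of col-73, col-17, dpy-13, dpy-5, dpy-4, col-125, Y47D7A.13, cyp-35C1, fat-6, fat-5 and col-81 were each lost, with adjusted p from 0.51 to 1 and from 0.066 to 0.29. All but col-73 were lost without rotenone replicate 1 as well (0.093 to 0.81), and col-17, dpy-5, dpy-4 and Y47D7A.13 without DMSO replicate 2 (0.059 to 0.12). Y47D7A.13 had adjusted p = 0.051 without DMSO day 10 replicate 1.

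Whether rotenone affected the same genes at different ages was asked by 12 overlaps of called genes. Days 5 and 10 shared 47 lower genes against 1.2 by chance, among them sdz-14, sdz-28, fbxb-75, btb-8 and the autophagy substrate gene sepa-1. Days 1 and 10 shared 5 higher genes, C14C6.5, cdr-2, F01D5.5, pqn-74 and T20G5.8, against 0.28 by chance. Days 1 and 5 shared 2 higher genes, clec-82 and F09C8.1, against 0.067. Other genes passed in opposite directions, 5 at days 1 and 5 (col-120, F41G3.10, lys-7, thn-2 and Y51H7C.13), 3 at days 1 and 10 (C52D10.1, pho-11 and Y9C9A.16) and 8 at days 5 and 10 (asns-2, clx-1, col-183, F35E12.5, F52E1.14, hmit-1.1, pqn-75 and T28F4.5). Day 1 shared no lower gene with day 5 or 10. Fold changes of days 5 and 10 had a correlation of 0.225 across genes, and the other 5 pairs lay between -0.04 and 0.08. With a mean of at least 50 counts it was 0.121 for days 1 and 5 and 0.233 for days 10 and 20. For days 5 and 10 it was 0.017 without DMSO day 10 replicate 3 and 0.048 with no filter. The 0.009 of days 1 and 10 may rest on DMSO day 10 replicate 1, without which both followed length (-0.537 and -0.385). Counts by chance take genes as independent, which they are not, and all ages share 1 fit, so no p is given.

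Whether the rotenone effect followed the change with age was asked by its correlation across genes with an age change that shared no library with it. The correlation was 0.135 at day 1, 0.103 at day 5, -0.265 at day 10 and -0.162 at day 20. With no filter on low counts these were 0.04, 0.023, -0.08 and -0.041, and with a mean of at least 50 counts 0.171, 0.029, -0.407 and -0.225. Over left-out libraries they ran from 0.004 to 0.194, 0.07 to 0.148, -0.277 to -0.183 and -0.173 to -0.079. The value of 0.004 at day 1 came without DMSO day 10 replicate 1, and the day 20 value was -0.079 and -0.097 without rotenone day 20 replicates 1 and 2.

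Whether the rotenone effect differed between ages was asked by the interaction in edgeR. The effect at day 5 differed from that at day 1 for 82 genes, 11 with a higher and 71 with a lower log2 difference, that at day 10 for 60 genes, 27 and 33, and that at day 20 for 7 genes, 5 and 2. Collagens made up 12 of the lower genes at day 5, and 18 lower and 1 higher passed when adjusted over the list alone (median log2 difference -0.22, adjusted p = 0.00061, and 0.75 with an estimated correlation). Early embryo genes had a median log2 difference of -0.43 at day 5 and -0.42 at day 10, with 1 and 0 of 37 lower in edgeR and 7 and 5 lower when adjusted over the list alone (adjusted p = 0.00012 and 3.4e-05, and 0.095 and 0.088 with an estimated correlation). Of 90 immune effectors 3 had a lower effect at day 5, lys-7 and thn-2 among them (median -0.32, adjusted p = 0.00011, and 0.75 with an estimated correlation). DAF-16 induced genes had a median of -0.35 at day 5, with 2 of 10 lower, dod-3 and dod-6 (adjusted p = 0.0012, and 0.2 with an estimated correlation). The collagen, embryo, immune and DAF-16 lists kept these calls with each library of the days compared left out. The length trend of day 1 enters each of these differences, whose Spearman correlations with length were 0.427, 0.408 and 0.435 across genes. With the trend removed the day 5 median was -0.12 for collagens (adjusted p = 0.0023, and 0.84 with an estimated correlation), -0.08 for immune effectors (0.033 and 0.76) and -0.44 for DAF-16 induced genes (0.00083 and 0.27). Early embryo genes then had -0.27 at day 5 and -0.36 at day 10 (0.003 and 0.00093, and 0.27 at both with an estimated correlation).

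Other lists were called in these differences, each with adjusted p of at least 0.75 with an estimated correlation but the heat shock list with 0.41. At day 5 germline (0.24, adjusted p = 0.001), muscle (0.17, 0.0067), ABC exporter (0.15, 0.017), vitellogenin (0.33, 0.041) and branched-chain catabolism genes (0.13, 0.041) had a higher median, and sperm (-1.23, 0.00041), glutathione S-transferase genes (-0.16, 0.025, 1 of 46 lower) and ribosomal protein genes (-0.13, 0.045) a lower one. At day 10 germline (0.22, 0.0012), vitellogenin (0.71, 0.0022), ABC exporter (0.21, 0.0027), intestinal (0.36, 0.0048), oocyte (0.13, 0.017) and P450 genes (0.07, 0.041, 2 of 75 higher) were higher, and sperm genes (-1.16, 0.00064), histones (-0.41, 0.0019) and complexes II to V (-0.18, 0.017) lower. At day 20 no member of the 16 called lists passed. Intestinal (0.43, 0.0003), germline (0.37, 0.0003), proteasome (0.13, 0.00058), moulting (0.35, 0.0011), vitellogenin (0.88, 0.0012), ABC exporter (0.32, 0.0055) and citric acid cycle genes (0.26, 0.0069) were higher. So were glycolysis (0.2, 0.013), branched-chain catabolism (0.15, 0.013), muscle (0.32, 0.017), unfolded protein response (0.15, 0.017), oocyte (0.16, 0.025) and heat shock genes (0.24, 0.035). Histones (-0.27, 0.01), early embryo genes (-0.21, 0.02) and mitochondrially encoded mRNAs (-0.48, 0.037) were lower. With the trend removed germline and sperm genes kept their call at day 5 (adjusted p = 0.024 and 0.016), where ribosomal proteins turned direction (0.12, 0.00042). Oocyte, germline, sperm and intestinal genes kept it at day 10 (0.035, 0.028, 0.016 and 0.021), and 8 lists kept it at day 20, among them heat shock (0.0026), intestinal (0.0015) and proteasome genes (5.5e-08).

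With 1 library left out at day 5 vitellogenins lost their call without DMSO day 1 replicate 3 (adjusted p = 0.092), rotenone day 1 replicates 1 and 2 (0.083 and 0.064), DMSO day 5 replicates 1 and 2 (0.053 and 0.23), rotenone day 5 replicate 3 (0.17) and DMSO day 10 replicate 1 (0.08). Branched-chain catabolism lost it without DMSO day 1 replicates 1 and 3 (0.067 and 0.065), rotenone day 1 replicate 2 (0.055), DMSO day 5 replicate 2 (0.11) and rotenone day 5 replicates 1 and 3 (0.069 and 0.055). Ribosomal proteins lost it without DMSO day 1 replicate 1 (0.24), rotenone day 1 replicates 2 and 3 (0.36 and 0.42), DMSO day 5 replicates 1 and 2 (0.085 and 0.39) and rotenone day 5 replicates 2 and 3 (0.28 and 0.2), and ABC exporters without DMSO day 5 replicate 2 (0.091). At day 10 complexes II to V lost it without rotenone day 1 replicates 2 and 3 (0.056 and 0.066), DMSO day 10 replicate 3 (0.072) and rotenone day 10 replicate 1 (0.51). P450 genes lost it without DMSO day 1 replicate 1 (0.17), rotenone day 1 replicates 2 and 3 (0.073 and 0.065), DMSO day 10 replicates 1 and 3 (0.094 and 0.15) and rotenone day 10 replicates 1 and 3 (0.062 and 0.086). ABC exporters and intestinal genes lost it without DMSO day 10 replicate 1 (0.6 and 0.059). At day 20 vitellogenin, germline, intestinal, citric acid cycle and proteasome genes alone kept theirs throughout. Without DMSO day 20 replicate 1 the adjusted p was 0.34 for ABC exporters, 0.31 for muscle genes and histones, 0.15 for the unfolded protein response, 0.14 for branched-chain catabolism, 0.1 for heat shock and 0.09 for early embryo genes. Without DMSO day 20 replicate 2 it was 0.27 for oocyte genes, 0.21 for mitochondrially encoded mRNAs, 0.084 for moulting and 0.056 for early embryo genes. Without rotenone day 20 replicate 1 early embryo, oocyte, heat shock, mitochondrially encoded and glycolysis genes had 0.26, 0.16, 0.11, 0.093 and 0.05, and without replicate 2 histones and muscle genes had 0.12 and 0.051. Without DMSO day 1 replicate 1 mitochondrially encoded mRNAs and heat shock genes had 0.067 and 0.055, without replicate 2 the former had 0.077, and without replicate 3 muscle, oocyte and unfolded protein response genes had 0.081, 0.065 and 0.057. Heat shock, early embryo and muscle genes had 0.073 each without rotenone day 1 replicate 2, and mitochondrially encoded mRNAs 0.087 without replicate 3. Heat shock genes had 0.057 without DMSO day 10 replicate 1.

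In edgeR with the length trend removed 72, 109 (68 higher, 41 lower) and 14 genes passed in the differences of days 5, 10 and 20, of which 61, 48 and 6 were shared with the 82, 60 and 7 genes. The replicate term at each day gave 113 genes for day 10 and 34 for day 20, and both together 524 for day 10 (339 higher, 185 lower). No filter gave 575 (332 higher, 243 lower), 750 (517 higher, 233 lower) and 799 (683 higher, 116 lower), DESeq2 161 (38 higher, 123 lower), 198 (103 higher, 95 lower) and 37, and a fit of only the groups compared 1681 (1255 higher, 426 lower), 3 and 1949 (1540 higher, 409 lower). Without DMSO day 1 replicates 1, 2 and 3 the counts were 44, 51 and 42 for day 5, 15, 12 and 20 for day 10, and 1, 4 and 4 for day 20. Without rotenone day 1 replicates 1 and 3 they were 43 and 42, 17 and 14, and 4 and 4, and 28 for day 10 without replicate 2. For day 5 the count was 43 and 32 without DMSO day 5 replicates 1 and 2 and 48, 42 and 48 without rotenone day 5 replicates 1, 2 and 3. For day 10 it was 110 and 91 without DMSO day 10 replicates 1 and 2 and 23 and 12 without rotenone day 10 replicates 1 and 3. For day 20 it was 0 and 21 without DMSO day 20 replicates 1 and 2, with 1606 at an unadjusted p under 0.05 in the fit of all libraries and 37 in DESeq2, and 1 and 1 without rotenone day 20 replicates 1 and 2. Without DMSO day 10 replicate 1 it was 788 for day 5 (521 higher, 267 lower), where the balance turned, and 1196 for day 20 (989 higher, 207 lower). For day 10 the balance turned to more higher genes without DMSO day 1 replicate 2 (7 of 12), rotenone day 1 replicates 1 and 3 (12 of 17 and 8 of 14), DMSO day 10 replicate 1 (72 of 110) and rotenone day 10 replicates 1 and 3 (17 of 23 and 8 of 12).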

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

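The tests below of gene length, a shared batch, the oocyte list and day 1 adults among the collagens were chosen after the result was seen.

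The rotenone effect differed from that at day 1, by the interaction test of edgeR, for 82 genes at day 5, 60 genes at day 10 and 7 genes at day 20. For day 5 the named genes with a higher effect were dod-23 (log2 difference 1.6 ± 0.15 SE, adjusted p = 8e-06), oac-54 (1.46 ± 0.24, 0.0046), dhs-26 (1.43 ± 0.17, 0.00014) and F30H5.3 (1.3 ± 0.2, 0.0018). Those with a lower effect were rol-1 (-5.21 ± 0.42, 1.9e-06), col-49 (-4.81 ± 0.41, 2.3e-06), col-175 (-4.73 ± 0.5, 3e-05), dao-4 (-4.63 ± 0.89, 0.021), col-138 (-4.14 ± 0.35, 2.3e-06), dod-3 (-1.91 ± 0.37, 0.021), lys-7 (-1.33 ± 0.15, 8.1e-05), thn-2 (-1.29 ± 0.16, 0.00021), dod-6 (-1.12 ± 0.24, 0.04) and sdz-14 (-0.74 ± 0.16, 0.043). The lysozyme lys-7 stood at 92.5 ± 4.2 CPM with DMSO and 165 ± 21 CPM with rotenone at day 1, and at 1660 ± 61 and 1180 ± 44 CPM at day 5 (SD, n = 3). The calls of F30H5.3 and sdz-14 were lost with the length trend removed (log2 difference 0.94 with adjusted p = 0.11 for F30H5.3). Those of sdz-14 and dod-6 were lost without any 1 of the 12 libraries of days 1 and 5 (adjusted p from 0.054 to 0.16 and 0.051 to 0.13). The call of dod-3 was lost without DMSO day 1 replicates 1 and 3, rotenone day 1 replicate 3, DMSO day 5 replicate 2 and rotenone day 5 replicates 2 and 3 (0.052 to 0.087). That of dao-4 was lost without DMSO day 5 replicates 2 and 3 and each rotenone day 5 library (0.051 to 0.09).

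For day 10 the named genes with a higher effect were Y9C9A.16 (log2 difference 1.9 ± 0.28 SE, adjusted p = 0.004), oac-20 (1.7 ± 0.33, 0.028), grd-4 (1.45 ± 0.3, 0.042) and dod-17 (1.43 ± 0.3, 0.043). Those with a lower effect were F09G2.3 (-2.15 ± 0.29, 0.0025), B0205.13 (-1.68 ± 0.27, 0.0084), F53A9.8 (-1.5 ± 0.28, 0.022) and F13E9.15, now nssp-49 (-1.49 ± 0.27, 0.022). Each of these calls was lost when only the groups compared were fitted, with adjusted p between 0.05 and 0.14. Without any 1 of the 12 libraries of days 1 and 10 the call of dod-17 was lost (0.05 to 0.1). Those of grd-4 and F53A9.8 were lost without any day 1 library and without rotenone day 10 replicates 1 and 3, and that of grd-4 without DMSO day 10 replicate 3 (0.068 to 0.13 and 0.056 to 0.11). The call of oac-20 was lost without any day 1 library but rotenone replicate 2 and without rotenone day 10 replicates 1 and 3 (0.051 to 0.093). That of F13E9.15 was lost without DMSO day 1 replicates 2 and 3, rotenone day 1 replicates 1 and 3 and rotenone day 10 replicate 3 (0.053 to 0.082).

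For day 20 the named genes were col-73 (3.12 ± 0.55 SE, adjusted p = 0.046), glf-1 (2.62 ± 0.43, 0.023), F30H5.3 (1.8 ± 0.25, 0.011), T22B7.7 (1.36 ± 0.22, 0.023), gst-14 (-3.94 ± 0.7, 0.046) and B0205.13 (-1.89 ± 0.28, 0.011). Each call was lost without DMSO day 20 replicate 1 (adjusted p from 0.1 to 0.69) and rotenone day 20 replicate 1 (0.056 to 0.26), and each but that of F30H5.3 without rotenone day 20 replicate 2 (0.082 to 0.23). Those of col-73, glf-1 and gst-14 were lost without DMSO day 20 replicate 2 (0.055 to 0.096). Among day 1 libraries, calls were lost without any for col-73, any but rotenone replicate 2 for gst-14, DMSO replicates 1 and 2 and rotenone replicates 1 and 3 for glf-1, each DMSO library for T22B7.7, and DMSO replicate 1 for B0205.13 (0.051 to 0.15).

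The count of 82 at day 5 was reached by 2 of 100 splits of the libraries within each day, the real one included, with 155 genes in the highest other split. For day 10, 5 of 100 splits gave as many as the real 60 genes, with 5113 in the highest other split. These splits do not hold the rotenone effect of either day, so they do not test a difference between ages, and nothing about chance is drawn from them. The split with 155 genes and another with 234 at day 10 kept both treatment groups whole and exchanged them at day 1, so they add the 2 rotenone effects. The splits with 5113 and 4918 genes kept the day 1 groups whole and set DMSO day 10 replicates 2 and 3 with 1 rotenone library against the other 3, which points to a structure of the day 10 samples.

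Collagens differed with rotenone at days 5 and 20. The 13 collagens lower at day 5 would need a median of 12.5% (lowest 6.45%) of day 1 adults in the DMSO libraries. Genes of at least 100 CPM at day 1 and at least 50-fold lower in those libraries set a cap, which this choice keeps low. The 4 such genes (col-129, col-139, col-81 and col-93) allowed a median of 0.963% and at most 1.37%. The 6 collagens higher at day 20 would need 6.64% (lowest 3.3%) in the rotenone libraries, where 36 such genes allowed a median of 1.01% and at most 1.95%. Each caps the share, so these values argue against day 1 adults as the source. Larvae mixed into the DMSO libraries at day 5 or the rotenone libraries at day 20 stay open. The 10 moulting genes other than collagens had medians of -0.1 and -0.06, under the 0.2 set as the bound against larvae. But 9 of 10 stood above the collagen excess of 2.5 and 2.41 CPM, so their baseline may hide a small share and the bound was wrong. A change of collagen expression in the adults with rotenone stays open as well.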

How the results depend on the processing

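The replicate term at each day, the removed length trend, both together and the comparisons without DMSO day 10 replicate 1 that do not hold it were chosen after the data were seen. Of the values for single genes and correlations, 4593 kept direction and side of the threshold over the alternatives, 343 lost a call, 146 gained one, 9 reversed and 2 moved. The counts of the 3 age comparisons kept within 1.5 times under every alternative run, from 6705 to 11159. RLE size factors and the replicate number as 1 term over all days moved no count by 1.5 times. Left-out libraries took the calls of 272 single values and gave 42. With a library of a pair left out at day 20, the remaining library is assumed to vary like the other groups. In the day 20 interaction 7.46% of 67 simulated 1.5-fold changes were recovered.

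With no filter, which adds tests on scarce genes, the counts for rotenone were 1822 (542 higher), 339, 362 (169 higher, 193 lower) and 64 at days 1, 5, 10 and 20, the interactions gave 575 (332 higher, 243 lower), 750 (517 higher, 233 lower) and 799 (683 higher, 116 lower), and correlations with age were 0.023, -0.08 and -0.041 at days 5, 10 and 20. With a mean of at least 50 counts these were 0.029 at day 5 and -0.407 at day 10. With the replicate term at each day 2075 genes passed at day 1 (643 higher, 1432 lower), 20 at day 20, and 113 and 34 in the interactions of days 10 and 20. With the length trend removed 349 genes passed at day 10 and 109 and 14 in those interactions, and with the replicate term as well 648 at day 10 (223 shared) and 524 in its interaction (59 shared). DESeq2 gave 314 (137 higher, 177 lower), 371 (162 higher, 209 lower) and 37 genes at days 1, 10 and 20, and 161 (38 higher, 123 lower), 198 and 37 in the interactions. A fit of only the groups compared gave 5010 (2156 higher, 2854 lower), 0 and 3 genes at days 1, 10 and 20, and 1681 (1255 higher, 426 lower), 3 and 1949 in the interactions. The spread then came from these libraries alone. List calls with an estimated correlation numbered 3, 0 and 0 for rotenone, age and interactions, and 0 for rotenone without DMSO day 10 replicate 1, and fry gave 7, 79 and 4.

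Over left-out libraries the rotenone counts ran from 22 to 3082 at day 1, 46 to 308 at day 5, 47 to 2396 at day 10 and 0 to 63 at day 20, and the interactions from 32 to 788, 12 to 110 and 0 to 1196. The highest values but 63 came without DMSO day 10 replicate 1, where the coefficient of variation was 0.0911 in place of 0.135. With the length trend removed rpl-33 reversed to 0, rps-13 to -0.01, hsp-60 to 0.01 and vit-2 to 0.1 at day 1, and vit-2 to -0.1 in the day 5 interaction. Without rotenone day 10 replicate 1 gas-1 reversed to 0.01 at day 10, and without DMSO day 20 replicate 1 gst-4 reversed to -0.05 and vit-2 to -0.03 at day 20 and gst-4 to -0.08 in its interaction. Those values were 0.64, 0.72 and 0.61 without DMSO day 20 replicate 2, and gas-1 had -0.21 at day 10 without DMSO day 10 replicate 1. None of the reversed values had passed its test. Why the values moved with the filter and the other settings was not tested. Correlations between libraries of equal number were between 0.03 and 0.16 at days 1, 5 and 20 and between -0.14 and 0.16 between ages in DMSO. The replicate term changed no other list call of day 10 or its interaction than those given, besides P450 genes in the interaction (adjusted p = 0.1).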

Other observations

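The tests below of gene length, a shared batch and the oocyte list were chosen after the result was seen.

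With age in DMSO, further gene groups moved in ways not given above. Of 13 genes of branched-chain amino acid catabolism 10 fell at day 20 (median log2 change -1.29, adjusted p = 2e-05, and 0.19 with an estimated correlation). The member acdh-1 (I, 6497436 to 6499560), an acyl-CoA dehydrogenase, fell from 1250 ± 16 to 317 ± 20 CPM (SD, n = 3) at day 10, a log2 fold change of -1.98 ± 0.11 (SE). At day 20, 16 of 18 glycolysis genes (median -0.71, adjusted p = 0.00011, and 0.31 with an estimated correlation), 12 of 15 citric acid cycle genes (-0.6, adjusted p = 0.0013, and 0.52 with an estimated correlation), 23 of 41 fat metabolism genes with 6 higher (-0.45, adjusted p = 0.00095, and 0.19 with an estimated correlation) and 8 of 10 HIF-1 targets (-0.94, adjusted p = 0.0012, and 0.16 with an estimated correlation) fell. Of 26 autophagy genes 13 rose and none fell (0.34, adjusted p = 0.0033, and 0.19 with an estimated correlation), and of 26 histones, which share sequence, 18 rose and 4 fell (0.89, adjusted p = 0.0069, and 0.52 with an estimated correlation). The intestinal proteases asp-3 (X, 6791064 to 6792709) and cpr-1 (V, 11975551 to 11976756) fell at day 20 from 1430 ± 43 to 93.3 ± 7.4 CPM and from 438 ± 6.9 to 72 ± 1.9 CPM (SD, n = 3 and 2).

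Of 66 UDP-glucuronosyltransferases 41 fell and 11 rose at day 10 (median log2 change -0.62, adjusted p = 0.00071, and 0.47 with an estimated correlation), and ugt-30 fell from 6.34 ± 0.29 to 0.282 ± 0.016 CPM (SD, n = 3). The detoxification gene gst-4 fell at each later age, with log2 fold changes of -0.8, -1.93 and -1.96, and sod-3 with -0.86, -1.71 and -1.32. Of 10 DAF-16 induced genes 8 rose and 1 fell at day 5 (0.95, adjusted p = 0.0012, and 0.16 with an estimated correlation).

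The library DMSO day 10 replicate 1 stood apart from its group, and its deviation across genes had a Spearman correlation of -0.547 with exonic length, against -0.422 to 0.504 in the other libraries. This is consistent with a gene length bias, which is a hypothesis since it was tested on the same data, and with the lengths implied by the deposited RPKM the correlation was -0.076. Its 20 most abundant genes took 8.3% of the counts, inside the 7.78 to 24% of the other libraries, which argues against a few genes taking most of the counts. Its correlation with a change to another age was at most 0.079, which argues against a sample of another age. A handling or library batch shared with rotenone day 10 replicate 1 cannot be told apart from a bias of this library alone, since their deviations had a correlation of 0.429, between the bounds set, and the labels give no batch.

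Early embryo genes were lower with rotenone at days 5 and 10. With the libraries thinned to the lowest total of 25769159 the medians were -0.37 and -0.39 (adjusted p = 2.4e-08 and 9.5e-10), which argues against library depth. With the length trend removed the higher of the 2 medians was -0.32 (adjusted p of 0.029 and 0.011 with an estimated correlation), and with the replicate term as well the day 10 median was -0.41 (adjusted p = 4.2e-08, and 0.13 with an estimated correlation, against 0.18 with the replicate term alone), which argues against gene length bias as the whole source. The oocyte and eggshell list had medians of 0.02 and 0.07 with SD of 0.17 between members, so fewer oocytes are not a likely source. DMSO day 10 replicate 1 stays open for day 10. Without it the median was -0.28 (adjusted p = 0.3 with an estimated correlation), with fold changes following gene length. Fewer embryos, lower expression per embryo or other sources may underlie the pattern, and none was measured.

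Splits of the libraries of 3 against 3 number 10, the real one included, too few for a share under 0.05. The real split at day 1 gave 109 genes and the highest other 1, so 1 of 10 splits gave as many, and at day 5 the real split gave 148 and the highest other 3, with 1 of 10. At day 10 the real split gave 229 genes and 3 of 10 splits gave as many, with 2990 in the highest other. The splits with 2990 and 2645 genes put both replicate 1 libraries in 1 group and DMSO replicates 2 and 3 in the other, which points to a structure of the samples. The 2 other splits with both replicate 1 libraries in 1 group parted DMSO replicates 2 and 3 and gave 0 genes each, so replicate number alone does not account for it. Among the 4 splits that part every pair of equal numbers the highest other gave 1 gene, and with the replicate term 286 genes passed (94 higher, 192 lower). For age in DMSO, 1 of 10 splits gave as many as the real 9413 genes at day 5 and 9464 at day 10, with 0 in the highest other split of each.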
